A study of Mus musculus with 6 samples.

How the data were processed

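RNA of tooth germs from C57BL/6 mouse embryos (E15.5 per the labels) was sequenced on an Illumina NextSeq instrument, in 3 wild-type and 3 Smad7-/- libraries. Per the labels, RNA was taken with an RNeasy kit and 1 ug of total RNA went into a TruSeq RNA library kit, which does not record the strand. The authors aligned reads with HISAT2 to the mm10 genome and counted them with featureCounts, and DESeq2 is also named, all without versions. The deposited tables hold raw counts per gene symbol, whole numbers with no normalization, 1 table per library. Of the 23420 symbols, 27 had been turned into dates by a spreadsheet program, and 2 of these occurred more than once; they hold at most 0.223% of the counts of a library. No mitochondrially encoded gene is in the tables.

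All fits used the 6 libraries, 3 per group, with no covariate, since no label says that a replicate number marks a shared litter or day. The correlations of residuals between libraries of the same number were 0.169, -0.03 and 0.09. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 15284, and library sizes were scaled by TMM, with factors from 0.984 to 1.02. The test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. The common dispersion was 0.0253, a biological coefficient of variation of 15.9%. CPM values are scaled by the TMM library sizes, and errors are SD over libraries for CPM and SE of the fit for log2 fold changes. Depth ran from 37591888 to 56575476 counts per library, and reads without molecular identifiers are not independent molecules.

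Named genes followed a rule written before the data were examined. They were Smad7, then up to 10 genes per direction with the largest change among genes past the threshold with a mean of at least 5 CPM and group ranges that did not overlap. Gene models were left out if their symbol was Gm and a number, began with LOC, or ended in Rik or -ps. Then came up to 4 members per list past the threshold, or the 2 most abundant members of a list with none. The same rule on the genes called by DESeq2, and members that passed over their list alone, were added after the data were seen. Some genes that these rules select are not reported here. Positions came from GENCODE M21, in which 98.8% of tested genes were found by symbol or synonym.

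Before the data were examined 37 gene lists were fixed, of which 35 with at least 5 tested members were tested by camera in limma 3.58.1 (preset correlation 0.01), adjusted over the 35 lists. Camera compares a list with all other genes, and the mean and median log2 changes of members were computed beside it. The mitochondrially encoded genes could not be tested, and sex-linked genes were read per library only. The dental lists share members, among them Shh, Sp6 and Cdkn1a. Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, other size factors, other filters, a fit that is not robust, the replicate number as a block, leaving out each library, other tissues' genes left out or used as a covariate, a 2-fold minimum, camera with an estimated correlation, and fry. Added after seeing the data were sex as a covariate, libraries with Y-linked reads alone, Smad7-/- library 3 alone against wild type, the split of the libraries as a covariate, older symbols of list members and an osteoclast list. A lone library is assumed to vary as the libraries of the other group do.

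The methods were tested on simulated data, 5 sets of 15284 genes with 100 genes changed by 1.5-fold and 100 by 2-fold. These were drawn from genes with a mean of at least 5 CPM, so recovery at lower levels was not measured. edgeR recovered 54.2% of the first and 93.8% of the second, with 9.29% of its calls false, and DESeq2 recovered 70.6% and 96.6%, with 17.4% false. A list raised 1.3-fold was called in 5 of 5 sets, with 1 other list called per set on average. Simulated genes were drawn independently, with no correlation within lists and no division of the libraries. These rates therefore do not carry over to lists whose members vary together. Figures were drawn with matplotlib 3.10.9.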

Results

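RNA of mouse tooth germs labelled E15.5 was sequenced in 6 libraries, 3 from wild-type embryos and 3 from Smad7-/- embryos. Smad7 encodes an inhibitory SMAD that restrains TGF-beta and BMP signalling, and the comparison asks which transcripts of the developing tooth differ when it is disrupted. The wild-type libraries held 52137318, 48911104 and 47800685 counts, and the Smad7-/- libraries held 37591888, 44021706 and 56575476. Of 23420 gene symbols, 15284 passed the filter on low counts and were tested, with a median standard error of 0.14 on the log2 scale. The labels do not state whether the libraries come from separate animals, so p-values measure only the spread between these samples. Wild-type library 1 and Smad7-/- library 3 carried Xist, the RNA that silences an X chromosome in female cells, at 195 and 365 CPM (counts scaled to library size). The other 4 libraries carried the Y-linked helicase gene Ddx3y at 117 to 166 CPM.

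The libraries also separated in a way that crossed genotype. Wild-type library 1 and Smad7-/- libraries 1 and 2 (called the first set here) lay between -32.3 and -15.2 on the first principal component, which held 33.5% of the variance. Wild-type libraries 2 and 3 with Smad7-/- library 3 (the second set) lay on the positive side, at up to 25.2. Between these sets edgeR called 358 genes, 141 higher and 217 lower in the first set, and none of the 4 genes called between genotypes was among them. Among the genes called, named after their values were seen, Pop4, a subunit of the RNase that trims transfer RNA precursors, was higher in the first set by 1.31 ± 0.14 (log2, SE). Ift80, a ciliary transport gene, and Ccnb2, a mitotic cyclin, differed by -1.36 ± 0.13 and -0.60 ± 0.07. Ribosomal protein genes were higher in the first set by a mean log2 of 0.29 and G2/M phase genes lower, with a mean of -0.30. Wnt signalling and nuclear-encoded respiratory chain genes were higher there too, with means of 0.19 and 0.11. The labels give no date or batch for these sets. Means within each set stand beside the called gene lists whose sign differs within either set, and beside the red blood cell, FGF and Wnt lists.

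Smad7 transcripts fell in Smad7-/- tooth germs to 0.0716 of the wild-type level, from 19.4 ± 1.77 to 1.42 ± 0.709 CPM (mean ± SD, n = 3 libraries per group; log2 fold change -3.80 ± 0.33 SE; edgeR adjusted p = 0.00749). The gene lies on chromosome 18 at 75367529 to 75395935 (mm10, forward strand). Its counts were 1097, 934 and 859 in the wild-type libraries and 80, 62 and 41 in the Smad7-/- libraries, so every library matched its genotype label. The call ended without Smad7-/- library 2 (-3.83, adjusted p = 0.0887) and with a skeletal muscle covariate (-3.73, adjusted p = 0.124), in a range over the alternatives from 4.17e-40 to 0.124.

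Besides Smad7, edgeR called 3 genes at an adjusted p under 0.05, for 2 higher and 2 lower in all. Pappa2, a secreted protease that frees insulin-like growth factors from their binding proteins, rose from 11.2 ± 1.65 to 27.3 ± 2.21 CPM (n = 3; log2 1.29 ± 0.14 SE; edgeR adjusted p = 0.0149). Ccnd1, the cyclin D that drives cells out of the first gap phase, fell from 21.4 ± 0.978 to 9.90 ± 1.40 CPM (n = 3; log2 -1.11 ± 0.14 SE; edgeR adjusted p = 0.0339). AA465934, an RNA annotated as a processed transcript whose span holds the small nucleolar RNA gene Snord7, rose 8.75-fold from 0.887 ± 0.143 to 7.79 ± 0.434 CPM (n = 3; log2 3.13 ± 0.21 SE; edgeR adjusted p = 4.87e-04). Its mean level is under the 5 CPM required of named genes, so it was singled out after its values were seen. Pappa2 lies on chromosome 1 at 158711727 to 158980490, Ccnd1 on chromosome 7 at 144929931 to 144939925 and AA465934 on chromosome 11 at 83291699 to 83294632. Ap2b1, an endocytosis adaptor gene near AA465934, did not pass, at -0.14 ± 0.10 SE, nor did Oraov1, which overlaps Ccnd1 on the opposite strand, at -0.07 ± 0.11. The Pappa2 call ended without wild-type library 1, Smad7-/- library 1 or Smad7-/- library 2 (log2 1.34, 1.35 and 1.29; adjusted p = 0.0566, 0.0674 and 0.191) and with a skeletal muscle covariate (1.33, 0.172). The Ccnd1 call ended without any single library (log2 -1.23 to -1.03, adjusted p = 0.0738 to 0.261) and with a skeletal muscle covariate (-1.02, 0.354). It also ended with sex as a covariate (-1.11, 0.115) and at a mean of at least 5 CPM (-1.11, 0.0604). The count of 4 genes became 2, 1 and 7 without Smad7-/- library 1, 2 and 3. Over all alternatives the adjusted p ran from 6.84e-14 to 0.387 for Pappa2, from 1.81e-10 to 0.387 for Ccnd1 and from 1.11e-38 to 0.133 for AA465934. Unadjusted p-values lay under 0.05 for 786 genes (499 higher, 287 lower) where 764 would be expected by chance. The ranges of the groups did not overlap for 1357 genes (8.88%), where chance gives 10%.

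**Figure D1:**
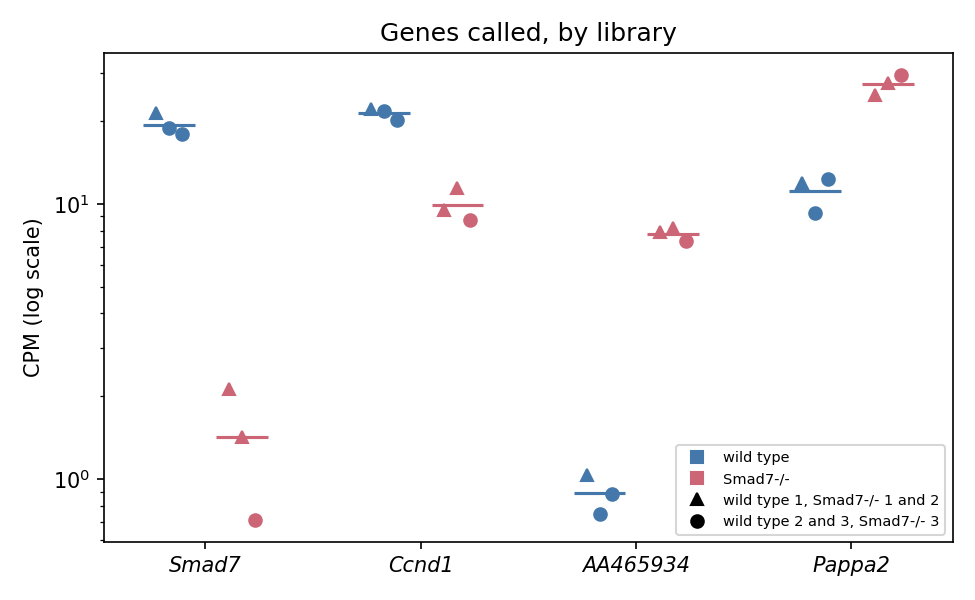
Normalised CPM (log axis) of the 4 genes called by edgeR in each of the 6 libraries, with wild type in blue, Smad7-/- in red, a line at each group mean, triangles for the first set of libraries and circles for the second. Smad7 averages 19.4 CPM in wild type and 1.42 in Smad7-/-, and for all 4 genes the ranges of the genotypes do not overlap.

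DESeq2 was run as an alternative on all 23420 symbols, with its own filter in place of the filter on low counts, so both tool and filter differed. It called 59 genes, 44 higher and 15 lower, which include the 4 genes above. Among them Ceacam19 and Tmem181c-ps had not been tested by edgeR. Tmem181c-ps, Lta and H2-K2, all called higher, lie on chromosome 17, where levels that differ among the Smad7-/- libraries are described below. Ctsk, the collagen-degrading cathepsin of osteoclasts, was higher in all 3 Smad7-/- libraries, with 255 ± 55.7 CPM in wild type and 477 ± 17.5 in Smad7-/- (n = 3; DESeq2 log2 0.90 ± 0.15 SE, adjusted p = 1.25e-05). Acp5, the tartrate-resistant phosphatase of the same cells, stood at 0.82 ± 0.17, and Sfpi1, which encodes the myeloid transcription factor PU.1, at 0.80 ± 0.19. Others on the higher side were Svep1, an extracellular matrix protein, at 0.85 ± 0.16 and Foxf2, a mesenchymal transcription factor downstream of Hedgehog, at 0.81 ± 0.17. Tfap2b, a transcription factor of the neural crest, was at 0.74 ± 0.19 and Fgfbp3, an FGF-binding protein, at 0.75 ± 0.18. The CDK inhibitor gene Cdkn1a was at 0.78 ± 0.18 and Cdk4, the kinase partner of cyclin D, at -0.86 ± 0.20, with Tspan31, which overlaps Cdk4, at -0.16 ± 0.12. On the lower side Aim2, a sensor of cytosolic DNA, stood at -0.52 ± 0.12 and Cyp26a1, which degrades retinoic acid, at -0.46 ± 0.12. The bicarbonate transporter gene Slc4a4 was at -0.45 ± 0.10, Cyb5d2 at -0.65 ± 0.16, AI464131 at -0.58 ± 0.15 and Esyt3 at -0.43 ± 0.11. None of these 15 genes passed in edgeR, where their adjusted p ran from 0.380 for Ctsk to 0.608 for Tfap2b and Cyp26a1. Over all alternatives that of Ctsk ran from 1.25e-05 to 1.00 and that of Tfap2b from 0.0341 to 1.00. On simulated counts 17.4% of DESeq2 calls and 9.29% of edgeR calls were false. Those counts held 200 changed genes and 1 list raised 1.3-fold among 15284 genes, and no division of the libraries, so these shares do not carry over to the calls here. Splits of the 6 libraries that mix the genotypes gave DESeq2 0 to 29 genes, apart from 1467 between the first and second sets.

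Of 35 gene lists fixed before the data were examined, camera with its preset correlation called 19, of which 12 rose and 7 fell relative to other genes. With an estimated correlation 0 passed (smallest adjusted p = 0.262; 5 lists had an unadjusted p under 0.05), and by fry 0 passed (smallest adjusted p = 0.277; 5 lists unadjusted). The lists hold 868 distinct tested genes, of which 100 had an unadjusted p under 0.05, edgeR called 0 over all genes and DESeq2 called 12. Counts of single members below are therefore those adjusted over the list alone, with 0 over all genes in each list.

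Dental mesenchyme genes, which mark the neural crest cells that condense around the tooth epithelium, rose as a list in Smad7-/- tooth germs. Their mean log2 was 0.35, with 24 of 26 members higher (camera adjusted p = 7.58e-15; adjusted p = 0.262 with an estimated correlation). Adjusted over the list alone, 8 members passed, all higher. Prrx1, a homeobox gene of craniofacial mesenchyme, went from 73.7 ± 9.10 to 109 ± 10.5 CPM (n = 3; log2 0.57 ± 0.11 SE). Osr2, a regulator of where teeth form, stood at 0.69 ± 0.21, Tfap2b at 0.74 ± 0.18 and Runx2, the master regulator of bone cells, at 0.43 ± 0.11. Twist1, Pax9, Lhx6 and Barx1, further transcription factors of this tissue, ranged from 0.36 to 0.55. The abundant members Dlx2 and Wnt5a stood at -0.09 ± 0.14 and 0.08 ± 0.11. Matrix genes rose with a mean of 0.21 (26 of 29 higher; adjusted p = 1.36e-08, and 0.347 with an estimated correlation), with Col1a1 and Col1a2, the chains of type I collagen, at 0.09 ± 0.18 and 0.09 ± 0.19; without Smad7-/- library 3 the matrix mean was 0.13. Bone and odontoblast genes did not pass (mean 0.08, adjusted p = 0.0751, and 0.629 with an estimated correlation), nor did cartilage genes (mean 0.13, adjusted p = 0.351). With the split of the libraries as a covariate the bone and odontoblast list passed (mean 0.13, adjusted p = 4.95e-04), as it did without wild-type library 3 or Smad7-/- library 1 (0.18 and 0.15; adjusted p = 9.55e-05 and 0.00231) and with a skeletal muscle covariate (0.10, 0.0384). It passed in 2 of 6 fits that left out 1 library, and its lowest mean there was 0.00481, without Smad7-/- library 3. Without wild-type library 3 the cartilage list passed (0.23, adjusted p = 0.0347), while its lowest mean without 1 library was 0.0284. The cartilage genes Col11a1 and Col11a2 were at 0.04 ± 0.16 and -0.11 ± 0.18. Red blood cell genes moved the other way in the same libraries, with a mean of -0.96.

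Macrophage and other immune cell genes also rose in Smad7-/-, with a mean log2 of 0.37 and 18 of 21 members higher (camera adjusted p = 2.42e-12; adjusted p = 0.301 with an estimated correlation). Adjusted over the list alone 9 members passed, all higher. Csf1r, the receptor for the growth factor that maintains macrophages, went from 39.2 ± 7.89 to 64.6 ± 6.54 CPM (n = 3; log2 0.72 ± 0.14 SE). The lysosomal marker Cd68 stood at 0.60 ± 0.14, the complement genes C1qa, C1qb and C1qc ranged from 0.51 to 0.73, and Laptm5, Tyrobp, Fcer1g and Mrc1 from 0.54 to 0.66. Endothelial genes were all higher (22 of 22, mean 0.27; adjusted p = 3.77e-07, and 0.555 with an estimated correlation), with the junction genes Cdh5 and Pecam1 at 0.22 ± 0.14 and 0.22 ± 0.13. The endothelial mean was 0.12 without wild-type library 2 and 0.42 without wild-type library 3. Smooth muscle and pericyte genes rose with a mean of 0.27 (14 of 16 higher; adjusted p = 7.19e-05, and 0.262 with an estimated correlation), Acta2 being at 0.43 ± 0.24. Schwann cell genes rose with a mean of 0.21 (10 of 17 higher; adjusted p = 0.0406, and 0.563 with an estimated correlation), although Itga4 and Mbp stood at -0.19 ± 0.12 and -0.01 ± 0.13. Their call ended without wild-type library 1 (mean 0.0937, adjusted p = 0.482) or Smad7-/- library 3 (0.0857, 0.640), and the mean was 0.38 without wild-type library 3. It also ended by DESeq2 (0.20, adjusted p = 0.0742), at a mean of at least 5 CPM (0.0152, 0.890) and with a skeletal muscle covariate (0.22, 0.125).

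Red blood cell genes fell as a list, with all 11 tested members lower and a mean log2 of -0.96 (camera adjusted p = 5.76e-11; adjusted p = 0.262 with an estimated correlation). The mean was -1.73 within the first set of libraries and -0.29 within the second. The abundant members Sptb, a spectrin of the red cell membrane, and Tmcc2 differed little, at -0.25 ± 0.16 and -0.03 ± 0.12. Without Smad7-/- library 3 the mean was -1.67. Neuronal genes did not pass (mean -0.18, adjusted p = 0.0657, and 0.563 with an estimated correlation); Nhlh1, a neurogenic transcription factor at 0.554 ± 0.0750 CPM in wild type, passed adjusted over the list alone at -1.57 ± 0.41. Skeletal muscle genes (mean -0.19, adjusted p = 0.214) and genes of keratinised epithelium (mean -0.10, median 0.00, adjusted p = 0.518) did not pass either, and the most abundant muscle gene, Neb, reached only 3.39 ± 0.541 CPM. Without Smad7-/- library 2 the neuronal, muscle and keratinised lists passed (means -0.30, -0.45 and -0.36; adjusted p = 0.00773, 0.00495 and 0.0244). The muscle list also passed without wild-type library 2 (-0.28, 0.0230) and with no filter (-0.27, 0.0483), the neuronal list with library totals (-0.17, 0.0491) and the keratinised list without wild-type library 3 (-0.37, 0.0168). The means nearest 0 without 1 library were -0.0259 for the neuronal, -0.0717 for the muscle and -0.00399 for the keratinised list.

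Dental epithelium genes fell slightly as a list, with 27 of 37 members lower and a mean log2 of -0.09 (camera adjusted p = 0.00102; adjusted p = 0.563 with an estimated correlation). Krt5, a keratin of basal epithelial cells, was at 4285 ± 246 CPM in wild type and 3925 ± 489 in Smad7-/- (n = 3; log2 -0.13 ± 0.13 SE). Sp6, a transcription factor needed by ameloblasts, was at -0.26 ± 0.11. The list no longer passed without Smad7-/- library 3 (mean -0.04, adjusted p = 0.424). Enamel protein and ameloblast genes fell with a mean of -0.13 (11 of 16 lower; adjusted p = 5.20e-04, and 0.262 with an estimated correlation). Amelx, which encodes the main enamel matrix protein, stood at -0.53 ± 0.26 and Enam, another enamel matrix gene, at -0.72 ± 0.29. Their mean was 0.15 within the first set of libraries and -0.42 within the second, and the call ended without Smad7-/- library 3 (mean -0.0762, adjusted p = 0.184). Without wild-type library 1 the mean was -0.21, and without wild-type library 3 it was -0.0473. With a skeletal muscle covariate the enamel call ended (-0.0381, adjusted p = 0.0539). Genes of the enamel knot, the signalling centre that shapes the crown, did not pass (mean 0.04, median -0.03, adjusted p = 0.923); among them Cdkn1a passed adjusted over the list alone.

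Targets of SMAD2/3, the transcription factors of the TGF-beta branch, rose in Smad7-/- by a mean log2 of 0.17, with 19 of 25 members higher (camera adjusted p = 1.66e-05; adjusted p = 0.262 with an estimated correlation). Ctgf, a matricellular growth factor, went from 70.4 ± 11.6 to 114 ± 17.05 CPM (n = 3; log2 0.70 ± 0.14 SE), and its relative Cyr61 from 10.6 ± 1.15 to 16.3 ± 1.75 (log2 0.62 ± 0.14). These 2 members passed adjusted over the list alone. The list shares 3 members with the matrix list and 2 with the smooth muscle list, which also rose. Its rise can therefore not be read as TGF-beta output alone. The abundant members Fn1, fibronectin, and Col4a1, a basement membrane collagen, stood at 0.36 ± 0.14 and 0.20 ± 0.12. Targets of SMAD1/5, the BMP branch, did not pass (mean 0.12, median 0.00 on the negative side, adjusted p = 0.181, and 0.629 with an estimated correlation). The BMP feedback genes Smad6 and Bambi stood at 0.00 ± 0.10 and -0.06 ± 0.10, and Dlx3 at -0.08 ± 0.09, while Cdkn1a, at 0.78 ± 0.17, passed adjusted over the list alone. The SMAD1/5 list passed in the libraries with Y-linked reads alone (mean 0.19, adjusted p = 0.0405), where genotype and the split of the libraries cannot be told apart. Without 1 library its mean ran from 0.0718 (without wild-type library 3) to 0.17, and it did not pass. Ligands, receptors and other parts of both pathways did not pass (mean 0.06, adjusted p = 0.146), with the receptor genes Bmpr1a and Tgfbr2 at 0.00 ± 0.10 and -0.07 ± 0.09.

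Hedgehog signalling genes rose as a list, with a mean log2 of 0.14 and 14 of 19 members higher (camera adjusted p = 0.00214; adjusted p = 0.347 with an estimated correlation). Adjusted over the list alone 3 passed on the higher side and 1 on the lower. Hhip, a decoy that binds the ligand, went from 95.4 ± 16.1 to 154 ± 24.2 CPM (n = 3; log2 0.69 ± 0.15 SE), and the target genes Foxf2 and Foxf1 stood at 0.81 ± 0.17 and 0.51 ± 0.12. The ligand gene Shh, made by the dental epithelium, went the other way, from 546 ± 55.3 to 422 ± 37.2 CPM (-0.37 ± 0.11). Ptch1, the receptor and a direct target, was at 0.14 ± 0.12. Wnt signalling genes rose with a mean of 0.19 (25 of 32 higher, camera adjusted p = 8.54e-06, and 0.347 with an estimated correlation). Ctnnb1, which encodes beta-catenin, stood at -0.09 ± 0.12 and the secreted inhibitor gene Wif1 at 0.10 ± 0.13. The Wnt list differed as much between the first and second sets of libraries (0.19, camera adjusted p = 0.00234). Its genotype mean was 0.11 within the first set and 0.20 within the second. With the split of the libraries as a covariate the Wnt list still passed (0.15, camera adjusted p = 8.77e-04). FGF signalling genes rose with a mean of 0.24 (18 of 23 higher; adjusted p = 0.00629, and 0.347 with an estimated correlation), with the receptor genes Fgfr1 and Fgfr2 at -0.06 ± 0.11 and 0.07 ± 0.10. The FGF mean was 0.03 within the first set of libraries and 0.43 within the second. The FGF call ended without wild-type library 3 (mean 0.21, adjusted p = 0.281) or Smad7-/- library 3 (0.15, 0.188), and at a mean of at least 5 CPM (0.0760, 0.169). With a skeletal muscle covariate the FGF and Hedgehog calls ended (means 0.15 and 0.10; adjusted p = 0.281 and 0.125). Eda and NF-kB signalling genes (mean -0.01, adjusted p = 0.904) did not pass, nor did Notch signalling genes (mean 0.01, adjusted p = 0.541), whose test pointed down while their mean and median were above 0.

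Proliferation genes fell as lists but not within both sets of libraries. G2/M phase genes were lower for 52 of 53 members with a mean log2 of -0.13 (camera adjusted p = 3.77e-07; adjusted p = 0.565 with an estimated correlation). S phase genes were lower for 41 of 45 members with a mean of -0.11 (adjusted p = 5.20e-04, and 0.608 with an estimated correlation). The G2/M mean was -0.21 within the first set of libraries and 0.10 within the second, and the S phase mean -0.31 and 0.12. Top2a, the topoisomerase of dividing cells, was at -0.25 ± 0.18 and Rrm1, which makes deoxynucleotides, at -0.20 ± 0.12. The S phase call ended without wild-type library 1 (mean -0.0595, adjusted p = 0.435) or Smad7-/- library 1 (-0.0506, 0.131), and the mean was -0.18 without wild-type library 3 and -0.22 without Smad7-/- library 3. The G2/M mean was -0.0880 without wild-type library 2, and -0.0710, -0.0476 and -0.30 without Smad7-/- library 1, 2 and 3. CDK inhibitor and growth arrest genes did not pass (mean 0.07, median 0.00 on the negative side, adjusted p = 0.702), nor did p53 targets (mean 0.03, median -0.01, adjusted p = 0.533). Cdkn1a passed adjusted over each of these lists alone, as did Ddit4l, an inhibitor of growth signalling through mTOR, among the p53 targets (0.66 ± 0.12). Apoptosis genes (mean -0.09, adjusted p = 0.146) and replication-dependent histone genes (mean -0.12, adjusted p = 0.146) did not pass, although the histone list passed without Smad7-/- library 2 (-0.18, 0.0360). Without Smad7-/- library 1 the histone mean was 0.0212.

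Among lists of general cell physiology, ribosomal protein genes rose by a mean log2 of 0.07, with 73 of 80 members higher (camera adjusted p = 0.00586; adjusted p = 0.792 with an estimated correlation). Rplp0 and Rpl4 stood at 0.12 ± 0.36 and 0.11 ± 0.14. The ribosomal mean was -0.05 within the first set of libraries and -0.01 within the second, and the call ended without wild-type library 2 or 3, or Smad7-/- library 1 or 2 (means 0.0152, 0.0134, 0.05 and -0.00759; adjusted p = 0.503, 0.860, 0.141 and 0.843). Without wild-type library 1 or Smad7-/- library 3 the ribosomal mean was 0.18 and 0.15. Immediate early and stress genes rose with a mean of 0.12 (17 of 24 higher; adjusted p = 0.0149, and 0.563 with an estimated correlation), with Klf4 at 0.07 ± 0.13. They no longer passed without wild-type library 3, Smad7-/- library 1 or Smad7-/- library 2 (means 0.0805, 0.10 and 0.11; adjusted p = 0.279, 0.0794 and 0.111), or with the split of the libraries as a covariate (0.0874, 0.106). The ribosomal call ended with that covariate too (-0.0289, 0.106). Cholesterol synthesis genes fell with a mean of -0.09 (16 of 19 lower; adjusted p = 0.0177, and 0.629 with an estimated correlation), Hmgcs1 being at -0.03 ± 0.10. Hypoxia and glycolysis genes fell with a mean of -0.09 (16 of 24 lower; adjusted p = 0.0185, and 0.563 with an estimated correlation), Pkm being at -0.11 ± 0.10. The cholesterol call ended without wild-type library 1 or 2 or Smad7-/- library 1 (means -0.0751, -0.0181 and -0.0431; adjusted p = 0.198, 0.522 and 0.308), and the mean was -0.17 without wild-type library 3. The hypoxia call ended without wild-type library 1, Smad7-/- library 1 or Smad7-/- library 3 (means -0.0778, -0.0308 and -0.0884; adjusted p = 0.296, 0.419 and 0.180), and the mean was -0.16 without Smad7-/- library 2. With a skeletal muscle covariate the hypoxia call ended (-0.0320, 0.626). Respiratory chain genes encoded in the nucleus (mean -0.02, adjusted p = 0.201) and interferon response genes (mean -0.04, median 0.03, test upwards, adjusted p = 0.923) did not pass. The respiratory chain list passed with the split of the libraries as a covariate (mean -0.0585, adjusted p = 2.30e-04), and without wild-type library 2 or Smad7-/- library 2 (-0.0519 and -0.0887; adjusted p = 0.00451 and 8.51e-06). Its mean was above 0, and it did not pass, without wild-type library 1, Smad7-/- library 1 or Smad7-/- library 3 (0.0119, 0.00174 and 0.0336). The interferon list passed without wild-type library 3, with its mean above 0 (0.18, adjusted p = 0.0289), and its mean was -0.16 without wild-type library 2.

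**Figure D2:**
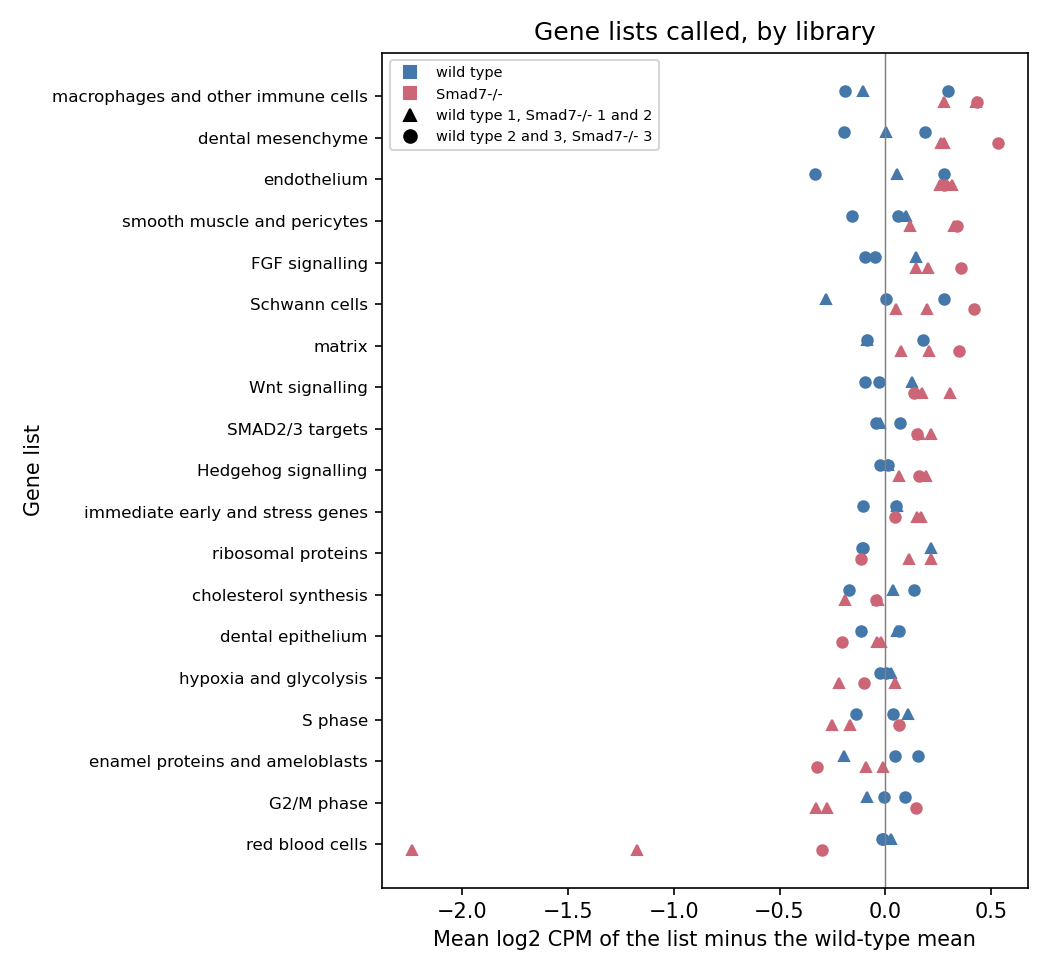
Mean log2 CPM of each of the 19 lists called by camera with its preset correlation, per library and relative to the wild-type mean, with wild type in blue, Smad7-/- in red, triangles for the first set of libraries and circles for the second. Dental mesenchyme and macrophage genes average higher in Smad7-/- (mean log2 changes of 0.35 and 0.37), with macrophage ranges that overlap (Smad7-/- library 1 at 0.28, wild-type library 3 at 0.30), and red blood cell genes lower (-0.96), while none of the 19 lists passed with an estimated correlation.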

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

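Sex as a covariate, the Y-linked libraries alone, Smad7-/- library 3 alone, the split of the libraries as a covariate and older symbols of list members (19 lists called, as before) were chosen after seeing the data, and no cause was tested unless stated. The 43 genes named as called by either tool or over a list alone kept their direction under every alternative run (812 values on the same side of the threshold, 28 newly past it, 18 no longer past it). These 43 were picked for their change in these same libraries, so a kept direction is no separate evidence. The same 4 genes were called by limma-voom, with RLE size factors, library totals, no filter, a fit that is not robust, other tissues' genes left out and the split as a covariate. They were also called with the replicate number as a replicate block, which gave Smad7 at -3.87. The 4 genes (2 higher, 2 lower) became 59 (44 and 15) by DESeq2, which was run without the filter on low counts. They became 2 (1 and 1) at a mean of at least 5 CPM, where AA465934 is filtered out and Ccnd1 missed the threshold (-1.11, adjusted p = 0.0604). With the skeletal muscle score as a covariate 1 (1 and 0) was called, and Smad7 was at -3.73 with an adjusted p of 0.124. Leaving out 1 library gave 1 to 7 genes (1 to 5 higher, 0 to 2 lower), with Smad7 between -4.21 and -3.46, and without Smad7-/- library 2 it was at -3.83 (adjusted p = 0.0887). The other counts were 3 (2 and 1) with sex as a covariate, 54 (15 and 39) in the Y-linked libraries alone and 2 (1 and 1) for Smad7-/- library 3 alone. The Y-linked libraries are wild-type libraries 2 and 3, of the second set, and Smad7-/- libraries 1 and 2, of the first, so genotype and the split of the libraries cannot be told apart there. The 19 lists became 0 with an estimated correlation and 0 by fry. In the Y-linked libraries alone 6 of the list calls ended: Hedgehog, dental epithelium, Schwann cells, matrix, hypoxia and cholesterol.

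Mean log2 changes of some lists turned sign, most of them lists that had not been called; the cause was not tested. With DESeq2, run without the filter on low counts, the enamel knot list stood at -0.320 and neurons at 0.149. With edgeR and no filter they stood at -0.343 and 0.180, so the DESeq2 values cannot be put down to the tool. At a mean of at least 5 CPM keratinised epithelium was at 0.106 and interferon response at 0.0843. With the skeletal muscle covariate enamel knot was at -0.0466, interferon response at 0.0722 and the respiratory chain at 0.0595. Leaving out 1 library, means ran from -0.0570 to 0.119 for enamel knot, -0.156 to 0.182 for interferon response (adjusted p = 0.0289 at the upper end) and -0.00759 to 0.179 for ribosomal proteins. They ran from -0.0887 to 0.0336 for the respiratory chain, with 0.0119 and 0.00174 between, and from -0.265 to 0.0212 for histones. In the Y-linked libraries alone bone was at -0.00215, cartilage -0.0134, Schwann cells -0.0337, keratinised epithelium 0.108 and the respiratory chain 0.0561. For Smad7-/- library 3 alone S phase was at 0.0525, G2/M 0.139, CDK inhibitors -0.0194 and p53 targets -0.0524. Enamel knot was then at -0.384, interferon 0.0878, ribosomal proteins -0.127 and histones 0.0740. G2/M (adjusted p = 5.97e-05) and ribosomal proteins (adjusted p = 4.36e-05) were thus called the other way. Newly called there were skeletal muscle (-0.707, adjusted p = 0.00247), keratinised epithelium (-0.851, 4.00e-04), the respiratory chain (-0.127, 1.63e-07) and bone (0.0842, 4.00e-04). The split as a covariate put ribosomal proteins at -0.0289. Called in all 6 fits that left out 1 library were 10 lists: SMAD2/3 targets, G2/M phase, Hedgehog, Wnt, dental mesenchyme, smooth muscle, endothelium, red blood cells, macrophages and matrix. In simulated counts edgeR found 54.2% of single genes changed 1.5-fold at a mean of at least 5 CPM. Its recovery of single genes with smaller changes or lower means was not measured.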

Other observations

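The tests of sex, tissue shares and linked blocks, the comparison of wild-type library 1, the genes near Smad7, the split as a covariate and the osteoclast list itself were chosen only after the results they address were seen. DESeq2 also called the next 6 genes, each named after its values were seen. Cyp26b1, an enzyme that degrades retinoic acid, was at 2.17 ± 0.359 CPM in wild type and 5.64 ± 1.84 in Smad7-/- (n = 3 libraries; log2 1.37 ± 0.29 SE). Its relatives Cyp26c1, whose group ranges overlapped, and Cyp26a1 were at -1.10 ± 0.28 and -0.46 ± 0.12. The Wnt inhibitor Frzb was at 39.5 ± 10.1 CPM in wild type and 66.0 ± 5.25 in Smad7-/- (log2 0.74 ± 0.17), Sfrp1, another, at 0.63 ± 0.17 and the BMP inhibitor Nbl1 at 0.68 ± 0.15, while the Wnt inhibitor Wif1, at 0.10 ± 0.14, was not called. edgeR called none of the 6; their adjusted p there ran from 0.521 for Cyp26b1 to 0.785 for Cyp26c1. Of the other cyclin D genes, Ccnd2 was at -0.30 ± 0.20 and Ccnd3 at 0.29 ± 0.11, and Cdk6, the second kinase partner of these cyclins, at 0.40 ± 0.27, with neither tool calling them.

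Enamel and dentin genes were among the most abundant transcripts of all 6 libraries. Of 15284 tested genes, Amelx ranked 3 by mean level (8488 CPM, from 5999 to 13709 over the libraries), Enam 9, Dspp, which encodes the main non-collagen protein of dentin, 17 and Ambn, another enamel matrix gene, 18. Collagen gene Col1a1 ranked 1 at 11989 CPM. Amtn and Klk4, which serve later enamel maturation, ranked 13484 and 13065, at 0.912 and 1.29 CPM. Odam and Mmp20, further members of the enamel list, were not low, at ranks 790 and 545 with 228 and 295 CPM. Enamel and dentin matrix are products of differentiated ameloblasts and odontoblasts, which form late in tooth development. These levels sit oddly with the E15.5 of the labels, and the stage rests on the labels alone. Of 90 genes within 10 Mb of Smad7, 5 (5.56%) had an unadjusted p under 0.05, against 5.17% elsewhere (Fisher's exact test, two-sided p = 0.810).

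More osteoclasts or their precursors may be present in Smad7-/- tissue, a hypothesis raised by Ctsk, Acp5 and Csf1r, which DESeq2 called and edgeR did not. In an osteoclast list written afterwards, 16 of the 18 genes other than the 5 seen first were higher, with a mean log2 of 0.50. The camera p was 2.04e-10 with a preset correlation and 0.0346 with an estimated correlation, neither adjusted with the 35 lists. Calcr, at 2.23 ± 0.86, rested on Smad7-/- library 1 (6.41 CPM, against 0.690 and 0.937 in libraries 2 and 3), while the median of the 18 genes was 0.53. Ctsk differed by 1.32 within the first set of libraries and 0.73 within the second, and Acp5 by 1.35 and 0.58. Mmp9, a matrix-degrading protease, was at 265 ± 74.1 CPM in wild type and 394 ± 46.8 in Smad7-/-, and Ocstamp, which serves cell fusion, at 2.32 ± 0.609 and 4.11 ± 0.469 (n = 3). The most abundant gene of the list, Sh3pxd2a, was at -0.07 ± 0.12, and it and Clcn7 are expressed by many cell types. Csf1r also stands in the macrophage list, and the surrounding jaw bone is a place where osteoclasts form, so a change in what was dissected stays open beside a change in the tooth.

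The first pattern weighed is the division of the libraries across genotype, in which wild-type library 1 with Smad7-/- libraries 1 and 2, against the other 3, gave 358 genes by edgeR and 1467 by DESeq2, where the genotypes gave 4 and 59. Gene length bias as the whole cause is argued against. Removing a length trend per library left 743 genes between the sets, which hold 316 of 375 called before. These 375 were called when only the 15105 genes of known length were used, against 358 among all genes tested. The difference between the sets had a Spearman correlation of -0.15 with exonic length, so a part played by length stays open. Sex as the whole cause is argued against too, because each set holds 1 library with Xist reads. Strain variants in linked blocks stay open, as 38.9% of these genes had another within 1 Mb where 95% of random draws gave 34.5% to 46.8% (permutation p = 0.701). Litter, stage and handling, which the labels do not give, stay open too, untested.

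A second pattern is the rise of dental mesenchyme, macrophage, endothelium and matrix lists in Smad7-/-. A lower share of epithelium in the dissected tissue would raise the markers of every other cell type alike. The 9 such lists spread over 1.33 on the log2 scale, from 0.37 for macrophages to -0.96 for red blood cells, which argues against it as the cause for all 9. That gap rests on red blood cells, a list whose 2 most abundant tested members, Sptb and Tmcc2, were at -0.26 ± 0.16 and -0.03 ± 0.12. Neuronal and skeletal muscle lists stood at -0.18 and -0.19 and cartilage at 0.13, none of them called. Dental mesenchyme, macrophage, endothelium, smooth muscle and Schwann cell lists rose by 0.21 to 0.37, and for these a lower share of epithelium stays open. The bone and odontoblast list, which is not among the 9, stood at 0.08 and was not called. The dental epithelium list itself stood at -0.09, and at -0.04 without Smad7-/- library 3. Sex of the embryos as the whole cause is argued against, since 1 library with Xist reads is found in each genotype. An effect of the Smad7 genotype on these cells and a change in blood and stroma taken with the tooth both stay open, untested.

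The last pattern is the level of Glo1, a detoxifying enzyme on chromosome 17, which was 186 and 188 CPM in Smad7-/- libraries 1 and 2 and 83.8 to 89.3 in the other 4. H2-T10, a gene of the MHC on the same chromosome, was at 6.97 and 8.60 CPM in those libraries and 0.104 to 0.272 in the others. Tmem181c-ps, also there and called by DESeq2, was at 2.45 and 1.45 CPM against 0.0838 to 0.174. The 7 genes that edgeR called without Smad7-/- library 3 included all 3 of these, so some genotype calls follow this pattern. Lta and H2-K2, MHC genes called by DESeq2, were also raised in Smad7-/- library 3 (0.660 and 0.781 CPM). A strain variant could account for the Glo1 level, since a duplication that spans Glo1 is known to vary among inbred strains. Glo1 ends at 30626871 and H2-T10 starts at 36115876, so a duplication at Glo1 need not reach H2-T10. The level of H2-T10 would then need a further variant linked to it. The same strain is given for all embryos, so such variants would require material from another strain, which was not tested. Of 111 other MHC interval genes 26.1% had both libraries beyond the other 4 on the same side, against 19.4% elsewhere (Fisher's exact test, two-sided p = 0.0906). Glo1 itself lies outside that interval. Within 0.5 Mb of it 2 of 3 genes did so, too few for a test, which leaves the strain variant open. The division of the libraries is argued against, as wild-type library 1 had a Glo1 level 1.04 times the mean of the other wild-type libraries.

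There are too few splits (10) of the 6 libraries into 3 and 3 to reach a share under 0.05. For edgeR, 2 of the 10 splits, the real one included, called as many genes as the genotypes (4, highest other 358), for DESeq2 2 did (59, highest other 1467), and for gene lists 1 did (19, highest other 17). Every split that mixes the genotypes called lists, from 4 to 17, so a list call with the preset correlation does not by itself point to genotype. The split that called several times the real count is that of the first pattern above and points to a structure of the samples. With it as a covariate edgeR called the same 4 genes.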
